A study of Mus musculus with 12 samples.

How the data were processed

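RNA-seq was carried out on RAW264.7, a mouse macrophage-like cell line, in 12 libraries. Per the labels, cells received either a control small interfering RNA (siRNA) or an siRNA against Synbindin, the protein encoded by Trappc4, and were collected without lipopolysaccharide (LPS, 0 h) or after 4 h with 100 ng/ml LPS. Each of the 4 groups held 3 libraries. The cells were used at passages 3 to 5 and the libraries kept strand information, per the labels' protocols. Replicates carry a number in the labels and nothing there says whether they came from separate transfections, so p-values measure the spread between these samples, which may be technical.

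The values used are gene FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library), as deposited by the authors in 1 table of 53801 Ensembl gene records with a gene symbol and 12 library columns. The submitters' processing notes name HISAT2, StringTie and the mouse build GRCm38, with no versions, roles or order. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Of the gene records, 53706 were found by ID in the GENCODE M21 annotation of GRCm38, which gave coordinates and transcript numbers. In the deposited table, 27 symbols had been turned into calendar dates, and these genes were identified by their Ensembl ID.

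FPKM values are not counts, so no count test was applied. The depth of each library was estimated from the deposited FPKM of genes with 1 annotated transcript. The most frequent low value of FPKM times transcript length in kb was taken as the step of 1 fragment. This gave 7.36 to 17.6 M (mega) fragments per library. In each library, 6.69% to 14.6% of low values lay within 1% of a whole number of steps, where 2% would by chance, so the deposited values are not plain fragment counts and the depths are rough.

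Genes with FPKM of at least 1 in at least 3 of the 12 libraries were tested, 13078 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with 1 mean per group over all 12 libraries and with empirical Bayes moderation along an intensity trend (8 residual degrees of freedom). Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. Tests were 2-sided, p-values were adjusted by Benjamini and Hochberg's method over the genes tested in each comparison, and an adjusted p under 0.05 was called. The comparisons were silenced against control cells without LPS, the same after LPS, LPS against none in control cells, LPS against none in silenced cells, and the difference between the last pair, called the interaction. For Trappc4, the FPKM of 3 against 3 libraries was also compared by a 2-sided exact permutation test, whose smallest possible p is 0.1. Overlaps of called genes were tested by Fisher's exact test, 1-sided.

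Gene lists, 31 in number, were fixed before the data were examined. They cover trafficking (TRAPP complex, ER-Golgi transport, unfolded protein response, lysosome and autophagy), the LPS response (Toll-like receptor 4 signalling, inflammatory cytokines, chemokines, interferon-stimulated genes, NF-kB feedback and targets, ERK-MAPK immediate-early and feedback genes, MAP kinase cascade components, inflammasome, antigen presentation), metabolism and stress (cholesterol synthesis, glycolysis, oxidative phosphorylation, Nrf2 and glutathione, p53 and apoptosis), the cell cycle (G1/S, G2/M), cell state (macrophage identity, alternative activation, osteoclast markers), other cell types (B, T and NK, neutrophil, fibroblast, epithelial), siRNA machinery, and RNA quality (mitochondrially encoded transcripts, ribosomal proteins). The 26 lists with at least 3 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over lists within a comparison, and again with an estimated correlation. Members that rose or fell were counted from the gene tests, adjusted over all genes and again over the list alone.

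The design, the alternatives and the rule for named genes were also fixed before the data were examined. The rule took Trappc4 in every library. For each comparison it took the 10 genes with the highest and the 10 with the lowest log2 fold change among called genes whose groups did not overlap, with a mean FPKM of at least 5 in a group compared and a symbol that is not a predicted, clone or pseudogene name. It further took 15 fixed genes of LPS signalling, and up to 4 called members of each list or, where none was called, the 2 with the smallest p. Genes named outside the rule are said to be so.

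The settings varied were a pseudocount of 0.1, no filter and a stricter filter on low values, 3 other scalings (a common sum per library, median-ratio scaling, quantile normalization), the replicate number as a block, a fit of only the groups compared, no intensity trend, a fold threshold of 2, and leaving out each library in turn. The estimated depth as a covariate was added after the data had been examined, as were the sum and quantile scalings and the left-out libraries for gene lists. The test was checked on simulated data made from the 13078 genes for the comparison of silenced and control cells without LPS. It found 17 of 67 genes (25.4%) changed by 0.5 on the log2 scale, 57 of 67 (85.1%) changed by 1, and 64 of 66 (97.0%) changed by 2, with 10 unchanged genes among 148 calls. With no gene changed, 0 were called for the comparison after LPS. The simulated noise was independent between genes and had the same spread per gene in all 12 libraries. The check therefore cannot show how the calls behave where spread differs with LPS or genes vary together.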

Results

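Gene expression was measured by RNA-seq in RAW264.7 macrophage-like cells. Synbindin, a subunit of the TRAPP vesicle-tethering complex encoded by Trappc4, was silenced, and cells were given LPS, the bacterial cell wall component sensed by Toll-like receptor 4. The 4 groups were cells with a control siRNA and cells with Synbindin siRNA (silenced cells), each without LPS and after 4 h of LPS, with 3 libraries per group. Values are FPKM as deposited by the authors, given as mean ± SD over n = 3 libraries. Log2 fold changes from limma are given ± SE. The libraries held between 11672 and 12351 genes at FPKM of 1 or more. Estimated depth without LPS was 9.12 ± 2.17 M fragments (M, mega) in control and 12 ± 4.41 M in silenced cells. After LPS it was 11.9 ± 1.55 M and 15.2 ± 2.14 M, so silenced libraries were on average deeper at both times. Within groups, Spearman correlations between libraries over genes were 0.958 to 0.972. The first principal component, with 69.6% of the variance, separated the 6 libraries with LPS from the 6 without.

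Trappc4 (ENSMUSG00000032112, GRCm38 chromosome 9, 44403698 to 44407600, minus strand, protein-coding with 7 annotated transcripts) was lower in every silenced library than in every control library of the same time. Without LPS, the control libraries had 14.1, 13.1 and 12.5 FPKM and the silenced libraries 4.35, 7.17 and 6.15 FPKM. The means were 13.2 ± 0.79 and 5.89 ± 1.43 FPKM, so 44.5% remained (log2 fold change -1.07 ± 0.19, 95% interval -1.49 to -0.64). After LPS, the control libraries had 13.8, 15.7 and 9.45 FPKM and the silenced libraries 5.86, 7.71 and 8.26 FPKM. The means were 13.0 ± 3.22 and 7.28 ± 1.26 FPKM, so 56.1% remained (log2 fold change -0.74 ± 0.19). Each exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow, and with limma Trappc4 did not pass adjustment over all genes (adjusted p = 0.0558 without and 0.120 with LPS). In the TRAPP complex list, 15 members were tested and 0 passed over all genes at either time, with Trappc4 the 1 member that passed when adjusted over the list alone. The list test gave adjusted p = 0.292 without LPS and 0.683 after LPS.

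**Figure D1:**
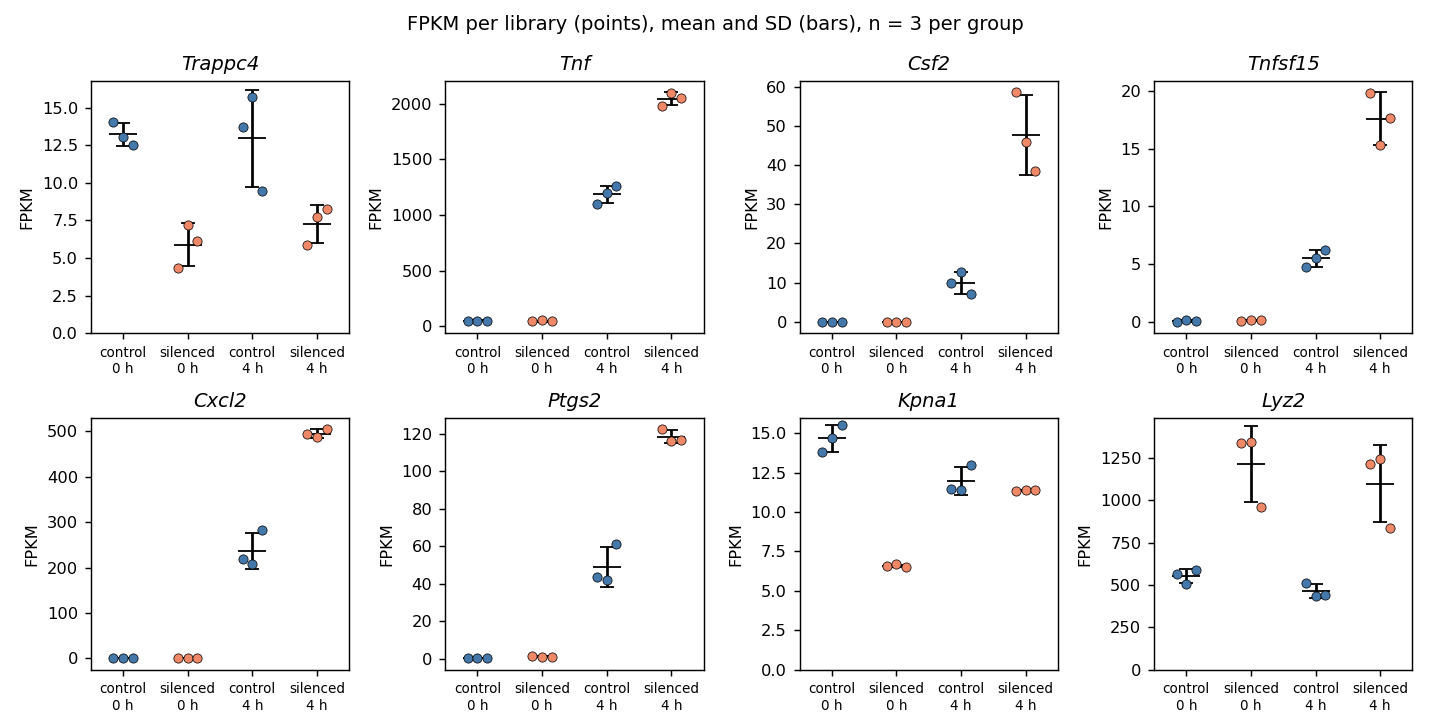
FPKM of 8 genes in each of the 12 libraries (points), with the mean (wide bar) and SD (error bars) of n = 3 libraries per group, on linear axes. Trappc4 lies lower in all silenced libraries of both times, Tnf, Csf2, Tnfsf15, Cxcl2 and Ptgs2 lie higher in silenced cells after LPS, Kpna1 is lower in silenced cells without LPS (14.7 against 6.59 FPKM), and Lyz2 is higher at both times.

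Without LPS, silenced cells had more lysozyme transcript, less of the nuclear import adaptor Kpna1 and less of the argonaute Ago1. Lyz1 was 50.5 ± 7.58 FPKM in control and 156 ± 8.50 FPKM in silenced cells (log2 fold change 1.62 ± 0.17, adjusted p = 0.00428). Its neighbour Lyz2 was 554 ± 41.1 and 1214 ± 222 FPKM (1.11 ± 0.17, adjusted p = 0.0283). Lyz1 and Lyz2 are near-identical copies on chromosome 10, so reads may have been split between them and each value alone is uncertain. Gas2l3, a cytoskeletal linker, rose from 9.38 ± 2.08 to 29.4 ± 2.88 FPKM (1.57 ± 0.13, adjusted p = 0.000459). Dynll1, a dynein light chain, rose from 17.8 ± 1.47 to 38.5 ± 3.23 FPKM (1.07 ± 0.16, adjusted p = 0.0283). Kpna1 fell from 14.7 ± 0.86 to 6.59 ± 0.07 FPKM (-1.04 ± 0.08, adjusted p = 0.000341). Further genes that rose were the tight junction gene Cldn11 (0.93), the sialic acid lyase Npl (0.80), the granule proteoglycan Srgn (0.68), the nucleotide receptor P2ry6 (0.51) and the thioesterase Acot7 (0.46). Genes that fell were Oas3 (-0.78), Rfng (-0.76), Ago1 (-0.73), Sidt2 (-0.53), Reep3 (-0.46) and Szrd1 (-0.40).

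Genes of cholesterol synthesis were shifted upward as a group in silenced cells without LPS. Of 26 tested members 22 had positive fold changes (median 0.27), 0 rose over all genes and 3 rose when adjusted over the list alone (list test adjusted p = 8.47e-06, and adjusted p = 0.0138 with an estimated correlation). The members with the smallest p were Cyp51, 15.5 ± 1.54 against 23.2 ± 0.54 FPKM (0.55 ± 0.10, adjusted p = 0.0607), and Msmo1, 19.4 ± 0.42 against 24.9 ± 2.16 FPKM (0.34 ± 0.07, adjusted p = 0.103). The list of siRNA machinery and double-stranded RNA sensors was shifted downward (14 tested, Ago1 fell, median -0.25, adjusted p = 0.000418, and adjusted p = 0.0364 with an estimated correlation). Its members Eif2ak2, Ifih1, Ddx58 and Dhx58 are also in the list of interferon-stimulated genes, so these lists are not independent. The macrophage identity list had adjusted p = 0.000154 with 2 of 25 members risen, Lyz1 and Lyz2, and 4 when adjusted over the list alone. It had adjusted p = 0.175 with an estimated correlation. Interferon-stimulated genes had a median of -0.43 over 56 tested members, of which Oas3 alone fell over all genes and 3 fell when adjusted over the list alone. The list test gave adjusted p = 4.53e-10, but adjusted p = 0.560 with an estimated correlation. Control replicate 3, 1 of the 3 control libraries, lay within the range of the silenced libraries. Osteoclast markers (median -0.15, Ocstamp fell by 0.90 on the log2 scale), the unfolded protein response (median 0.22), lysosome and autophagy genes (median 0.07) and mitochondrially encoded transcripts (median -0.13) had adjusted p = 0.0178, 0.0178, 0.0358 and 0.00565, and adjusted p = 0.560, 0.560, 0.560 and 0.570 with an estimated correlation. The mitochondrial share of FPKM was 17.8% ± 0.80 in control and 16% ± 0.76 in silenced cells. For inflammatory cytokines the median was 0.00, 0 of 21 passed and the list test gave adjusted p = 0.879. Members such as Csf2, Il6, Il10 and Ifnb1 were listed at 0 in all libraries without LPS. Their fold changes were therefore fixed at 0, so the list says little about cytokines that are silent without LPS.

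In all, 28 of 13078 genes were called without LPS, 16 higher and 12 lower, and 1565 had an unadjusted p under 0.05, where 654 would by chance. The call count was 6 when only the 6 libraries compared were fitted, 10 without the intensity trend and 48 with the replicate number as a block. It was 18 with libraries rescaled to a common sum and 9 with estimated depth as a covariate, chosen after the data were examined. Leaving out 1 library gave 3, 5, 10 and 4 calls without control replicates 1 and 2 and silenced replicates 1 and 2 of the untreated cells. The count was 8, 11 and 7 without control replicates 1 and 2 and silenced replicate 2 of the LPS-treated cells, which share the estimate of the spread. Lyz1, Gas2l3 and Kpna1 were called in each of these 12 fits. The other calls were lost more often: Ago1 was called in 7, Dynll1 and Oas3 in 6, Lyz2, Srgn and P2ry6 in 5, Reep3 and Szrd1 in 4, Npl and Acot7 in 3, Cldn11 and Ocstamp in 2, and Rfng and Sidt2 in 1.

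After 4 h of LPS, silenced cells had higher levels of inflammatory cytokine transcripts than control cells. Csf2, which encodes the growth factor GM-CSF, was 9.79 ± 2.81 FPKM in control and 47.7 ± 10.2 FPKM in silenced cells (log2 fold change 2.19 ± 0.19, adjusted p = 0.000709) and was listed at 0 in all 6 libraries without LPS. Those libraries add no spread to the estimate shared by all groups, so its SE and p may be too small. The same may hold for other genes near 0 without LPS. Tnfsf15, a TNF-family ligand, was 5.49 ± 0.75 and 17.6 ± 2.26 FPKM (1.52 ± 0.12, adjusted p = 0.000709). Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007) was 1185 ± 79.7 and 2043 ± 56.3 FPKM (0.79 ± 0.08, adjusted p = 0.00319), higher in 3 of 3 silenced libraries. Of 21 tested cytokine genes 20 had positive fold changes (median 0.42), 3 rose over all genes and 11 rose when adjusted over the list alone. The list test gave adjusted p = 4.86e-16, and adjusted p = 0.0135 with an estimated correlation. Members that did not pass over all genes included Il1b, 598 ± 131 against 962 ± 223 FPKM (0.68 ± 0.21, adjusted p = 0.184), and Il6, 4.77 ± 2.09 against 6.45 ± 2.40 FPKM (adjusted p = 0.566). Neither did Il10, 0.88 ± 0.21 against 1.42 ± 0.51 FPKM (adjusted p = 0.465), and Ifnb1, 1.86 ± 0.58 against 3.60 ± 0.72 FPKM (adjusted p = 0.106).

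Some chemokine, NF-kB target and macrophage genes also rose in silenced cells after LPS. In the chemokine list 2 of 17 members rose and 6 rose when adjusted over the list alone. The neutrophil attractant Cxcl2 was 237 ± 40.2 and 495 ± 9.23 FPKM (1.07 ± 0.16, adjusted p = 0.0214). The T cell attractant Ccl17 was 14.4 ± 1.70 and 27.9 ± 2.64 FPKM (0.91 ± 0.13, adjusted p = 0.0142). In the NF-kB list 3 of 36 rose and 11 rose when adjusted over the list alone. The first of the 3 was Ptgs2, the inducible cyclooxygenase, with 49.0 ± 10.9 FPKM in control cells (1.28 ± 0.16, adjusted p = 0.00946). The others were the inhibitor-like protein gene Nfkbiz (0.71 ± 0.14, adjusted p = 0.0477) and Zc3h12a, which encodes an RNase that degrades cytokine transcripts (0.68 ± 0.08, adjusted p = 0.00724). Both list tests gave adjusted p = 9.83e-08, and adjusted p = 0.0516 with an estimated correlation. Of 25 macrophage identity genes 5 rose, and 14 rose and 1 fell when adjusted over the list alone (median 0.35, adjusted p = 1.57e-09, and adjusted p = 0.0324 with an estimated correlation). Lyz1 (1.59), Lyz2 (1.22), the Fc receptor Fcgr1 (0.78) and the scavenger receptor Msr1 (0.61) were among them. Inflammasome genes had a median of 0.16, with 0 of 15 risen over all genes and 4 risen when adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.0450 with an estimated correlation). The members with the smallest p were Txnip (0.49, adjusted p = 0.119) and Casp1 (0.51, adjusted p = 0.120).

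Genes that fell in silenced cells after LPS included the NADPH oxidase Nox1, 9.79 ± 1.86 against 3.06 ± 0.66 FPKM (-1.41 ± 0.16, adjusted p = 0.00561), and the sialic acid-binding receptor Siglec15 (-1.30 ± 0.26, adjusted p = 0.0477). Others were the sulfur dioxygenase Ethe1 (-1.11), the phosphate antiporter Slc37a2 (15.5 against 7.19 FPKM), Snhg3 (-0.98), Ocstamp (-0.98), the oxysterol receptor Gpr183 (-0.81), Dennd5a (-0.69), Baiap2 (-0.66) and Pld4 (-0.64). Snhg3 overlaps Rcc1 and Snora73a on the same strand, so its value is uncertain. Of 10 osteoclast markers Ocstamp and Acp5 (-0.61 ± 0.10) fell (median -0.15, adjusted p = 0.0170, but adjusted p = 0.435 with an estimated correlation). Among other genes with the largest rises were the lipase Lipg (1.10), Snord104 (1.24), Spink5 (0.99) and Bcl6b (0.97). Interferon-stimulated genes (median 0.13), antigen presentation (0.16), alternative activation markers (0.12, Ccl17 rose) and cholesterol synthesis (0.08) had adjusted p = 0.00105, 0.000182, 0.0319 and 0.0306, and adjusted p = 0.801, 0.314, 0.139 and 0.110 with an estimated correlation. G2/M genes (median -0.24, adjusted p = 0.00106), ribosomal protein genes (0.12, adjusted p = 4.55e-06) and mitochondrially encoded transcripts (0.13, adjusted p = 0.00126) had adjusted p = 0.801, 0.435 and 0.508 with an estimated correlation. The mitochondrial share of FPKM was 12.7% ± 0.43 in control and 13.3% ± 0.50 in silenced cells.

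Receptor and kinase genes upstream of these targets gave no call. In silenced against control cells, Cd14, the LPS co-receptor, was 187 ± 13.9 and 291 ± 28.6 FPKM without LPS and 416 ± 103 and 601 ± 135 FPKM after LPS (adjusted p = 0.247 and 0.267). Log2 fold changes without and with LPS were -0.21 ± 0.12 and 0.16 ± 0.12 for Ly96, -0.21 ± 0.09 and 0.05 ± 0.09 for Myd88. They were 0.13 ± 0.15 and -0.20 ± 0.15 for Ticam1, and 0.09 ± 0.10 and -0.21 ± 0.10 for the kinase gene Mapk3. Tlr4 had values from 1.82 to 19.1 FPKM that varied more within groups than between them (adjusted p = 0.773 and 0.888). The lists of Toll-like receptor 4 signalling (32 tested, adjusted p = 0.740 and 0.999), MAP kinase cascade components (26 tested, 0.315 and 0.999), ERK-MAPK immediate-early and feedback genes (25 tested, 0.315 and 0.999) and ER-Golgi transport (54 tested, 0.0610 and 0.374) were not called at either time.

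In all, 94 genes were called after LPS, 41 higher and 53 lower, and 1697 had an unadjusted p under 0.05. Of the calls 43.6% were higher, against 60.5% with median-ratio scaling, 73.7% with quantile normalization and 32.1% with a common sum. The count rests on the spread estimated over all 12 libraries: with only the 6 libraries compared, limma called 0 genes (1622 at unadjusted p under 0.05). It called 38 with quantile normalization, 50 without the intensity trend and 18 with estimated depth as a covariate. Leaving out 1 library gave 15, 16, 20, 10 and 34 calls without LPS-treated control replicates 1 and 2 and silenced replicates 1, 2 and 3. It gave 46, 59, 53 and 55 without untreated control replicates 1 and 2 and silenced replicates 1 and 2. Csf2, Tnfsf15, Tnf, Zc3h12a, Nox1, Lipg and Lyz1 were called in each of the 12 fits that left out 1 library, whereas Bcl6b and Baiap2 were called in 1, Nfkbiz, Siglec15 and Slc37a2 in 2 and Fcgr1 in 3. Acp5 and Ethe1 were called in 5, Snhg3 and Pld4 in 6, and Cxcl2, Dennd5a, Spink5 and Snord104 in 7. Ocstamp and Msr1 were called in 8, Lyz2 and Ccl17 in 9, and Ptgs2 and Gpr183 in 11.

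**Figure D2:**
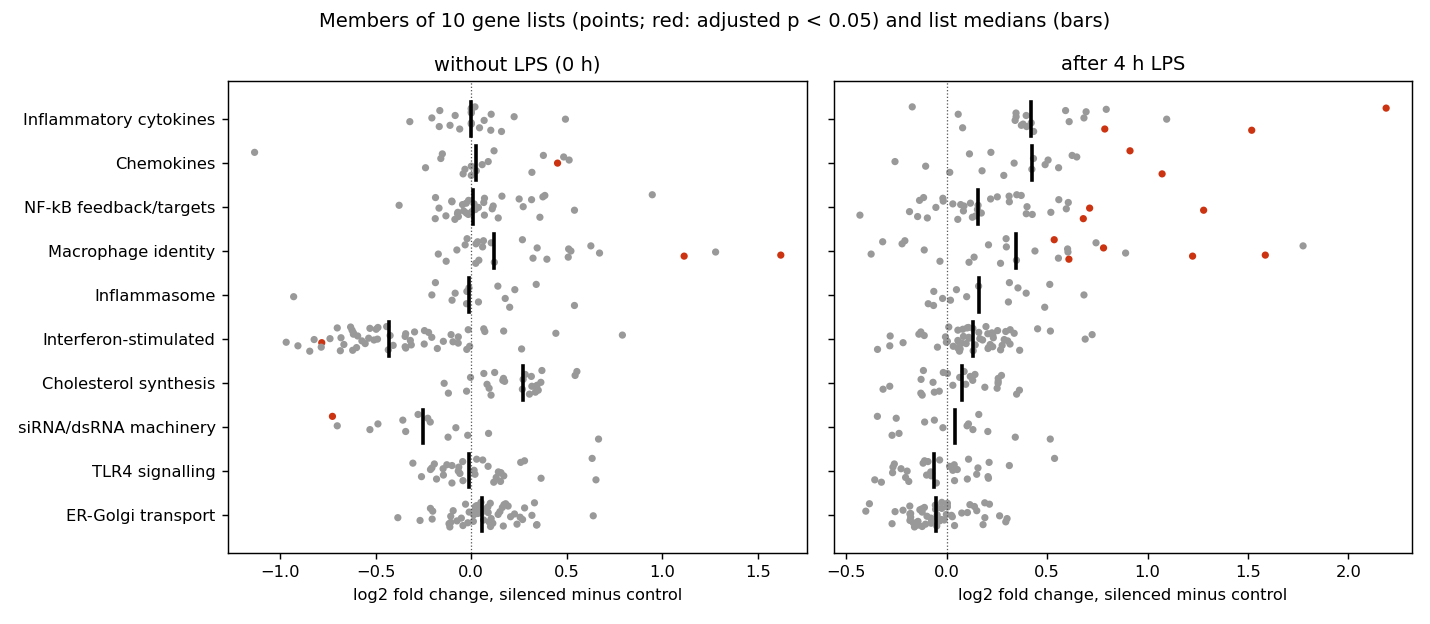
Log2 fold change of silenced minus control cells for the tested members of 10 gene lists (points, red where limma's adjusted p is under 0.05) and the list medians (black bars), without LPS (left) and after 4 h of LPS (right). The cytokine median moves from 0.00 without LPS, where some members were not detected, to 0.42 after LPS, and the interferon-stimulated median from -0.43 to 0.13.

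LPS itself changed nearly as many genes in control as in silenced cells: 6300 genes were called in control cells (1997 higher, 4303 lower) and 6337 in silenced cells (1698 higher, 4639 lower). In control cells the highest log2 fold changes were those of Il1a (9.05 ± 0.17), Il1b (8.79 ± 0.21), the itaconate-producing enzyme Acod1 (8.11 ± 0.26), Ccl22 (7.79 ± 0.23), Cxcl2 (7.06 ± 0.16), the antiviral gene Rsad2 (6.93 ± 0.46), Lif (6.75 ± 0.15), Ccl5 (6.41 ± 0.17), Ifit1 (6.19 ± 0.40) and Ifit2 (5.91 ± 0.42). Tnf rose from 50.4 ± 3.20 to 1185 ± 79.7 FPKM (4.53 ± 0.08), Nos2, the inducible nitric oxide synthase, from 0.07 ± 0.10 to 31.4 ± 8.11 FPKM (4.89 ± 0.18), and Cxcl10 by 5.67 ± 0.35 on the log2 scale. Il6, Il10 and Ifnb1 were listed at 0 in all libraries without LPS and reached 4.77 ± 2.09, 0.88 ± 0.21 and 1.86 ± 0.58 FPKM. In silenced cells the highest were Il1b (9.68), Il1a (9.17), Cxcl2 (8.18), Ccl22 (8.06), Rsad2 (7.56), Acod1 (7.51), Lif (7.24), Ccl5 (1.27 to 289 FPKM), Ifit1 (6.67) and Cxcl10 (6.47). Among receptor genes, Cd14 (1.12 and 1.02 in control and silenced cells), Myd88 (1.25 and 1.51) and Ticam1 (1.06 and 0.73) rose in both.

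Cell cycle genes fell with LPS in control and in silenced cells. In control cells 31 of 33 G1/S genes and 34 of 35 G2/M genes fell, with medians of -1.27 and -0.96, and in silenced cells 33 of 33 and 35 of 35 fell, with medians of -1.42 and -1.34. Examples in control cells were Cdc6, which loads the replicative helicase (-2.76 ± 0.14), Uhrf1 (-2.58 ± 0.28), E2f2 (-2.55 ± 0.14) and Mki67, the proliferation marker (-1.79 ± 0.24). The list tests gave adjusted p = 1.36e-07 and 8.60e-07 in control cells and 5.06e-09 and 2.38e-08 in silenced cells, but adjusted p = 0.411, 0.417, 0.339 and 0.345 with an estimated correlation. Outside these lists the lowest log2 fold changes in control cells were those of Tmem51 (-3.01), the hyaluronidase Hyal1 (-2.94), Angptl2 (-2.89), Ttc39aos1 (-2.87), Gmnn (-2.64), the Wnt receptor Fzd7 (-2.61) and the sphingosine phosphate receptor S1pr1 (-2.56). In silenced cells S1pr1 (-3.20), Tmem51 (-2.94), Kbtbd11 (-2.92 ± 0.97, with a wide spread), Rasa3 (-2.88), Angptl2 (-2.84), Klhl6 (-2.80), Wdhd1 (-2.79), Fzd7 (-2.72) and Gmnn (-2.68) were lowest.

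Inflammatory lists rose with LPS in nearly all tested members. All 21 tested cytokines rose in control and in silenced cells (medians 2.47 and 2.85), as did 16 of 17 chemokines (3.94 and 4.58), 34 of 36 NF-kB targets (2.23 and 2.31) and 55 of 56 interferon-stimulated genes (2.89 and 3.46). The cytokine list held 25 genes. Members not detected without LPS, such as Csf2 and Il6, passed the filter on low values only through libraries with LPS. The share of cytokines that rose is thus partly fixed by that filter. With an estimated correlation, adjusted p was 0.00273 and 0.00134 for cytokines, 0.00639 and 0.00423 for chemokines, 0.00273 and 0.00134 for NF-kB targets, and 0.0798 and 0.0399 for interferon-stimulated genes. Antigen presentation genes rose in 16 and 17 of 19 (Cd40 by 4.38 and 4.61, adjusted p = 0.0667 and 0.0361 with an estimated correlation). Cholesterol synthesis genes fell in 13 and 18 of 26 (Dhcr7 -1.75 and -1.82), with list test adjusted p = 0.0551 in control and 0.00870 in silenced cells, and adjusted p = 0.107 and 0.0399 with an estimated correlation. In ERK-MAPK feedback genes 12 rose and 9 fell of 25 in control cells, and 13 rose and 11 fell in silenced cells (Plaur 3.36 and 3.56, Myc 3.12 and 2.98, adjusted p = 0.107 and 0.0646 with an estimated correlation). The mitochondrial share of FPKM was 17.8% ± 0.80 without and 12.7% ± 0.43 with LPS in control cells, and 16% ± 0.76 and 13.3% ± 0.50 in silenced cells.

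The balance of rises and falls with LPS depended on the scaling. The median log2 fold change of all genes was -0.17 in control and -0.21 in silenced cells with FPKM as deposited and 0.02 in both with median-ratio scaling. The share of calls that were higher went from 31.7% to 53% in control cells and from 26.8% to 51.3% in silenced cells (42.6% and 40.2% with quantile normalization). The cell cycle and inflammatory medians kept their signs under the 3 other scalings, while the ribosomal protein list, called higher with FPKM as deposited (medians 0.05 and 0.16, adjusted p = 0.0219 and 6.95e-05, and adjusted p = 0.622 and 0.345 with an estimated correlation), had medians of -0.21 and -0.10 with quantile normalization.

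The interaction, which tests whether the LPS response differed between silenced and control cells, called 8 genes. The response was larger in silenced cells for Csf2 (2.19 ± 0.26 on the log2 scale, adjusted p = 0.0161), Tnfsf15 (1.42 ± 0.17, adjusted p = 0.0161), Kpna1 (0.98 ± 0.11, adjusted p = 0.0161), Zc3h12a (0.87 ± 0.12, adjusted p = 0.0271) and Tnf (0.85 ± 0.12, adjusted p = 0.0344). It was lower for Dynll1 (-1.61 ± 0.23, adjusted p = 0.0388), Gas2l3 (-1.54 ± 0.18, adjusted p = 0.0161) and the predicted gene Gm26377 (-0.59, chosen after its values were seen). For Csf2, Tnfsf15, Zc3h12a and Tnf the difference was seen after LPS, whereas Kpna1, Dynll1 and Gas2l3 differed without LPS. Csf2 was not detected without LPS, so its interaction restates its difference after LPS. After LPS Kpna1 was 11.9 ± 0.88 in control and 11.4 ± 0.04 FPKM in silenced cells, and Gas2l3 11.1 ± 0.64 and 11.3 ± 0.37 FPKM. Dynll1 was 26.8 ± 7.27 and 17.6 ± 0.43 FPKM after LPS, the opposite direction to that without LPS, though not called there (adjusted p = 0.179). With 1 library left out, these calls were kept in 8 of 12 fits for Kpna1 and Gas2l3, 7 for Csf2, 6 for Tnfsf15, 2 for Zc3h12a, 2 for Tnf and 1 for Dynll1. The cytokine list had a median interaction of 0.48 over 21 members, with 3 risen over all genes, 8 risen when adjusted over the list alone and 19 positive (adjusted p = 2.58e-11, and adjusted p = 0.0444 with an estimated correlation). Il1b (0.89, adjusted p = 0.326), Cxcl10 (0.80, adjusted p = 0.583), Ccl5 (0.59, adjusted p = 0.389) and Nos2 (0.49, adjusted p = 0.503) did not pass. Interferon-stimulated genes (median 0.57), chemokines (0.27), NF-kB targets (0.13) and antigen presentation (0.24) had adjusted p = 3.71e-13, 0.00267, 0.00215 and 0.000370, and adjusted p = 0.365, 0.266, 0.266 and 0.326 with an estimated correlation. Lists used as marks of RNA quality also had a positive interaction: mitochondrially encoded transcripts in 13 of 13 members (median 0.26, adjusted p = 1.18e-05) and ribosomal proteins (0.06, adjusted p = 0.0315), with adjusted p = 0.326 and 0.658 with an estimated correlation. The siRNA machinery (0.34), G2/M (-0.23) and ER-Golgi transport (-0.13) lists had adjusted p = 0.00618, 0.00778 and 0.0260, and adjusted p = 0.132, 0.662 and 0.226 with an estimated correlation. With median-ratio scaling 83.3% of the calls were higher, against 62.5%. The count was 5 with a pseudocount of 0.1, 3 with a common sum and 4 without the intensity trend. Leaving out 1 library gave 0 calls without LPS-treated control replicate 1 or any 1 of the LPS-treated silenced replicates 1, 2 and 3 (limma, with 1210, 1419, 1239 and 1367 genes at unadjusted p under 0.05). It gave 4 and 20 calls without LPS-treated control replicates 2 and 3, and 5, 3 and 5 without untreated control replicates 1 and 2 and silenced replicate 2.

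**Figure D3:**
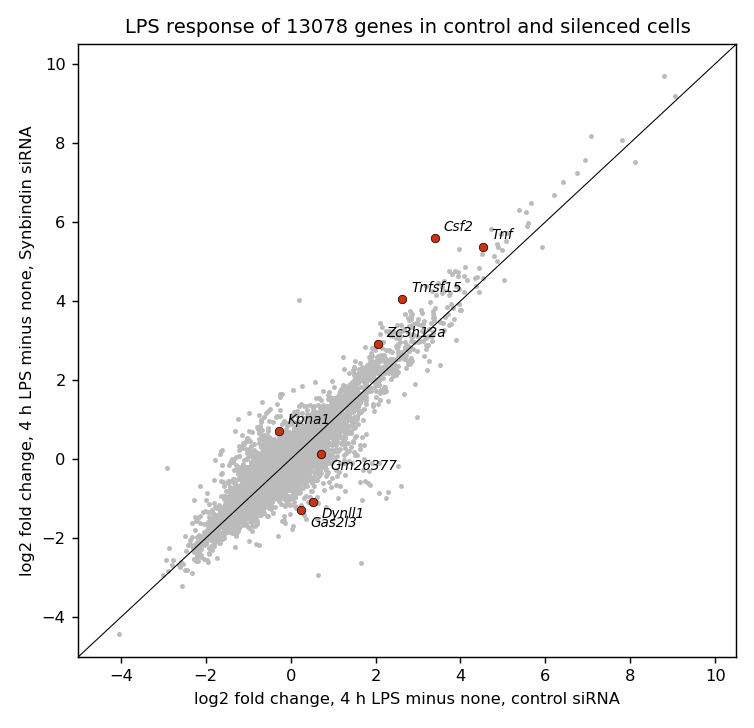
Log2 fold change of 4 h LPS against none for 13078 genes (points) in control cells (x axis) and silenced cells (y axis), with the line of equal change and the 8 genes called for the interaction in red. Csf2, Tnfsf15, Tnf, Zc3h12a and Kpna1 lie above the line, and Dynll1, Gas2l3 and Gm26377 below it.

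Across all genes the LPS responses of control and silenced cells had a Spearman correlation of 0.813, over genes that are not independent replicates. Of the calls, 1376 genes rose in both, 3558 fell in both and 15 changed in opposite directions, where independent lists would share 259 and 1526. The knockdown effects without and with LPS shared 6 called genes, all in the same direction: Lyz1, Lyz2, Srgn and Gm6166 were higher and Ocstamp and Sidt2 lower at both times (Gm6166 and, after LPS, Srgn and Sidt2 were named after their values were seen). The overlap exceeded that of independent lists, with 4 higher genes against 0.0502 (Fisher's exact p = 1.47e-07) and 2 lower genes against 0.0486 (Fisher's exact p = 0.00104). These p-values may be too small. Both comparisons use the same estimate of each gene's spread, which can raise the overlap by itself, and Lyz1 and Lyz2 may share reads. Over all genes, however, the knockdown effects of both times were nearly uncorrelated (Pearson r = 0.0590, Spearman rho = 0.0569). Most of these genes were not called at either time, so the correlation says little about those that were. Of the 28 genes called without LPS, 22 had the same sign after it. Of the 94 called after LPS, 74 had the same sign without it, over genes that are not independent.

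Markers of other cell types were low. Of 12 B cell markers 2 could be tested, with Ighm at most 20.5 FPKM and Blnk higher after LPS in control and silenced cells (0.97 and 1.10 on the log2 scale), and 10 stayed under 1 FPKM in all libraries. Of 16 T and NK cell markers 2 were tested (highest Cd5, 2.80 FPKM), and of 14 neutrophil markers 2 (highest Cebpe, 3.79 FPKM). Of 14 fibroblast markers 1 was tested (Tagln, 1.98 FPKM) and of 12 epithelial markers 0 (highest Cldn7, 1.07 FPKM), too few for a list test. With LPS, Lck (0.44 and 0.99) and Cd5 (0.55 and 0.72) also rose in control and silenced cells and Csf3r fell (-0.50 and -0.40), and Cebpe fell in silenced cells (-0.41). None of these tested markers was called between silenced and control cells.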

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

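The fit with estimated depth as a covariate was chosen after the data had been examined, and the other tests given here were set down before their results were seen. The results stood out because the LPS response differed between silenced and control cells by limma's interaction test.

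The response of inflammatory cytokine genes was larger in silenced cells, with a median interaction of 0.48 on the log2 scale, and with 2.19 for Csf2, 1.42 for Tnfsf15 and 0.85 for Tnf. With 1 library left out, the calls were kept in 7 of 12 fits for Csf2, 6 for Tnfsf15 and 2 for Tnf. The difference in the list mean after LPS was 0.59 (95% interval 0.43 to 0.75) with FPKM as deposited. It was 0.58 (0.39 to 0.78) with log2 depth as a covariate. However, every LPS-treated silenced library (13.5 to 17.6 M) was deeper than every LPS-treated control library (10.1 to 12.9 M). The covariate thus rests on variation of rough depths within groups, and deeper sequencing of the silenced libraries is not excluded. The scaling does not account for the difference in the list mean after LPS, which was 0.63 (0.43 to 0.83) after median-ratio scaling. All of these intervals pool the spread of the 12 libraries. As deposited, list means spanned 1.33 to 1.45 without LPS, and 4.51 to 4.76 in control and 5.14 to 5.31 in silenced cells after LPS. The untreated libraries thus add little spread, and the intervals may be too narrow. The list's median interaction lay at percentile 99.12 of 10000 random lists matched on the mean LPS response. Those lists had a median of 0.25 (central 95% 0.01 to 0.46). They were drawn gene by gene, without the correlation between cytokine genes, and the cytokine list was flagged by its interaction in these same libraries. The percentile therefore cannot decide whether all LPS-induced genes responded more strongly alike. The 751 genes with a mean LPS log2 fold change of at least 1 had a median interaction of 0.17, with 66.6% positive. A candidate explanation that these tests leave open is an effect of the Synbindin siRNA on cytokine transcripts, directly through Synbindin or through other transcripts that the siRNA may bind, which were not told apart. It is a hypothesis found in these 12 libraries and not itself tested, for which another siRNA or a rescue with Synbindin would be needed.

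Zc3h12a had an interaction of 0.87, called in 2 of 12 fits with 1 library left out. For Kpna1 the interaction was 0.98, with lower levels in silenced cells without LPS and similar levels after it. Gas2l3 had -1.54, with higher levels in silenced cells without LPS and similar levels after it. Dynll1 had -1.61, higher in silenced cells without LPS and lower after it (26.8 in control and 17.6 FPKM in silenced cells), and was called in 1 of 12 fits with 1 library left out and in 2 of 9 other fits. The predicted small gene Gm26377 had -0.59. Mitochondrially encoded transcripts also had a positive interaction (median 0.26), and whether RNA quality contributes to the cytokine difference was not tested.

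Swapping the siRNA labels within each time point made 200 splits, of which 100 were drawn. Only 1 of the 100, the real one, gave 8 or more called genes (highest other 7), a share under 0.05. This does not exclude chance for the interaction. Swapping mixes silenced and control libraries, so differences between them widen the spread within swapped groups. The count also fell to 0 without LPS-treated control replicate 1 or any 1 of the LPS-treated silenced replicates. The 6 libraries of every other comparison make 10 splits, too few for a share under 0.05. There the real split called 28 genes without LPS (highest other 3), 94 after LPS (highest other 4), 6300 for LPS in control cells (highest other 2) and 6337 for LPS in silenced cells (highest other 1).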

How the results depend on the processing

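The estimated depth as a covariate, and the sum, quantile and left-out-library settings for gene lists, were chosen after the data had been examined. A pair of transcript-level fits, the transcript with the highest mean FPKM per gene and each Trappc4 transcript alone, were not run because the deposited table holds 1 value per gene. The count of LPS calls stayed within 1.5 times of its value under each setting tried, except for the fold threshold of 2, which left 1769 in control and 1900 in silenced cells. The genes called changed more than the count did. With median-ratio scaling, 4849 of the 6300 calls in control cells and 4521 of the 6337 in silenced cells stayed called. Of the calls as deposited, 28 and 74 changed sign with that scaling, and 31 and 37 with quantile normalization. No named gene called with all libraries as deposited, or in the setting itself, reversed its direction under any setting run. Some named genes called in neither did change sign. Where a count fell with fewer libraries or a fold threshold, the setting itself leaves fewer degrees of freedom or genes. For the other changes the cause was not tested.

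The count of knockdown calls without LPS was 28, and 18 with a common sum, 10 without the intensity trend, 9 with the depth covariate, 6 with only the groups compared and 10 at 2-fold or more. After LPS it was 94, and 38 with quantile normalization, 50 without the intensity trend, 18 with the depth covariate, 0 with only the groups compared (limma, 1622 at unadjusted p under 0.05) and 13 at 2-fold or more. The interaction count was 8, and 5 with a pseudocount of 0.1, 3 with a common sum, 4 without the intensity trend and 4 at 2-fold or more. Leaving out each library in turn gave 3 (control replicate 1, 0 h) to 41 (control replicate 3, 0 h) calls without LPS, 10 (silenced replicate 2, 4 h) to 91 (silenced replicate 3, 0 h) after LPS, and 0 (control replicate 1 or any silenced replicate, 4 h) to 20 (control replicate 3, 4 h) for the interaction. It moved these counts by over 1.5 times for 7, 9 and 9 of the 12 libraries.

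With an estimated correlation 2 of 8 lists stayed called for the knockdown without LPS, 3 of 13 after LPS, 3 of 15 and 9 of 15 for LPS in control and silenced cells, and 1 of 10 for the interaction. Quantile normalization gave 5 lists without LPS and 9 for LPS in control cells, and the depth covariate 5 without LPS. Leaving out each library gave 8 (silenced replicate 3, 4 h) to 14 lists after LPS. The ribosomal protein list reversed with quantile normalization, to a mean log2 fold change of -0.16 (adjusted p = 0.0597) with LPS in control cells and -0.064 (adjusted p = 0.347) in silenced cells.

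Trappc4 without LPS passed the threshold with the stricter filter (-1.07, adjusted p = 0.0433) and with quantile normalization (-1.12, adjusted p = 0.0355), and ranged from -1.20 to -0.90 with 1 library left out, passing in 1 of these fits.

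The labels do not say that replicate numbers pair the samples. Of 18 same-number pairs of libraries 3, all among replicates numbered 3, had deviations correlated above 0.1 (range -0.03 to 0.19), so the numbers were not used as pairs. However, 8 of 12 libraries correlated best with their own number, a hint from the data and not from the design. As a block they gave 48 knockdown calls without LPS, 96 after LPS, 6558 and 6595 for LPS, and 10 for the interaction. Of the knockdown calls made without the block it kept 27 of 28 without LPS and 73 of 94 after LPS, and of the interaction calls 6 of 8.

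Small changes are often missed: in the simulation of the comparison without LPS on 13078 genes, 25.4% of changes of 0.5 on the log2 scale were found, so a gene without a call is not shown to be unchanged.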

Other observations

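The tests of same-strand overlaps, of transcripts in protein-coding genes and of the median of all genes, and the test of libraries within groups for interferon-stimulated genes, were chosen after the result was seen, and so were the genes of the next paragraph.

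A few genes outside the rule, too few to stand for a group, were called between silenced and control cells. Spp1, which encodes osteopontin, was 699 ± 34.1 in control and 1267 ± 199 FPKM in silenced cells after LPS (n = 3, log2 fold change 0.84, adjusted p = 0.0291), and 694 ± 47.6 and 1104 ± 191 FPKM without LPS (adjusted p = 0.0961). Cybb, the phagocyte NADPH oxidase subunit, was 112 ± 6.09 and 171 ± 15.7 FPKM after LPS (0.60, adjusted p = 0.0121), while the oxidase Nox1 was lower. Without LPS, the growth factor gene Igf1 was 1.47 ± 0.29 and 4.03 ± 0.59 FPKM (1.03, adjusted p = 0.0349). The lists of glycolysis, oxidative phosphorylation and Nrf2 gave no call between silenced and control cells at either time. Their adjusted p without and with LPS was 0.0808 and 0.999 for glycolysis, 0.438 and 0.999 for nuclear oxidative phosphorylation, where Sdha fell after LPS (-0.40), and 0.0939 and 0.999 for Nrf2 and glutathione. For p53 targets it was 0.563 and 0.374, with Ccng1 lower after LPS (-0.46).

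The list mean of interferon-stimulated genes differed by -0.374 between silenced and control cells without LPS, with a 95% interval that includes 0 (-0.878 to 0.130), and 1 of 56 members fell over all genes. A scaling factor, which moves all genes of a library alike, is argued against as the whole cause by the median log2 fold change of all tested genes, 0.00707, with an SD over genes of 0.270. Differences between libraries of the same group may account for it: control replicate 3 had a list mean of 2.28, inside the range of the silenced libraries (2.21 to 2.53), against 3.03 and 3.04 in the other control libraries, and the list test with an estimated correlation gave adjusted p = 0.560. Without control replicate 3 the difference was -0.624 (-0.988 to -0.260). These values compare libraries without regard to their numbers, whereas replicate 3 was lowest in both groups and each silenced library lay below the control library of its number (2.48 and 3.03, 2.53 and 3.04, 2.21 and 2.28), so an effect of the siRNA stays open.

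Some genes swung between libraries of the same group. Tlr4 ranged from 1.82 to 19.1 FPKM, and of 2 records named Septin 2 in the table the usually higher one was 9.76 and 13.6 FPKM in control replicate 3 and silenced replicate 1 after LPS and 49.8 to 65.9 FPKM in the others, while the other record rose to 19.7 and 19.2 FPKM. Counting noise is argued against by Tlr4's within-group SD of 1.07 on the log2 scale, above the upper end of the central range (0.535) of genes closest to it in FPKM times length. The top 1% of genes by spread had 2 or more annotated transcripts less often than the rest (37.7% against 83.3%, odds ratio 0.121, Fisher's exact p = 6.51e-19, over 7614 genes, and 85.3% against 92.8%, odds ratio 0.452, Fisher's exact p = 0.0304, over 6706 protein-coding genes). This cannot decide against division of reads among transcripts of a gene. Most protein-coding genes have 2 or more transcripts, and several top genes with 1, such as Gm28048, Exosc6 and Pet117, overlap another record on the same strand. Division of reads stays open, also for Tlr4, with 4 annotated transcripts, and the Septin 2 records, with 13 and 3. Sharing of reads between records that overlap on the same strand is a candidate explanation for part of the pattern, since 32 of 68 protein-coding genes in the top 1% (47.1%) had such an overlap against 8.89% of the rest (odds ratio 9.11, Fisher's exact p = 4.32e-16). The Septin 2 records overlap each other in this way, but Tlr4 has 0 such overlaps and its swings stay open.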
